A study of Mus musculus with 4 samples.

How the data were processed

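Gene expression was measured in the combined gastrocnemius and soleus muscles of male mice lacking corticotropin-releasing factor receptor 2 (Crhr2 KO) and of their wild-type littermates (WT), all aged 6.5 months and on a mixed C57BL/6 and 129 background. Total RNA of 4 mice per genotype was combined into 2 pools of 2 mice, per the labels' protocols, and each pool was hybridised after biotin labelling to 1 Affymetrix U74Av2 array, a 1-colour array that measures each transcript with a set of short probes. The groups were taken from the sample titles, because the labels exchange the contents of the genotype and tissue fields. The p-values for single probe sets below measure the spread between pools, not between single mice. Those for gene lists at a preset correlation rest mainly on the spread among genes. The p for genes near Crhr2 compares them with other stretches of genes.

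The deposited table holds 1 linear signal intensity per probe set and array, in arbitrary units. The authors' summary algorithm, background correction and detection calls are not given in the sources used here. The deposited intensities were already scaled between arrays: the mean without the lowest and highest 2% of probe sets was 200.2 in each of the 4 arrays, the form that global scaling to 1 target gives. Array medians were 69.2 and 68.4 in WT and 67.6 and 71.2 in KO and differed by 0.06 on the log2 scale, under the limit of 0.1 set for recentring, so no further scaling was applied. Ratios of 3' to 5' control signals, a measure of RNA integrity and labelling, were 0.624 and 0.686 in WT and 0.729 and 0.866 in KO for actin, and 0.889 and 0.914 in WT and 1.04 and 0.988 in KO for Gapdh. The number of arrays limits the precision.

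Of 12488 probe sets in the table, 66 Affymetrix controls were left out and 12422 were tested without a filter on level. Values were taken as log2(intensity + 14), the pseudocount being 20% of the table's median, so fold changes of dim probe sets are understated. A linear model of genotype was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05 (two-sided). Errors of log2 fold changes are standard errors from this fit, and group values are means ± SD of 2 arrays. A size rule with no p-value counted probe sets with at least a 2-fold difference on this scale, both KO arrays on the same side of both WT arrays and a mean above that of the median probe set.

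The platform annotation gave 1 gene symbol to 10833 probe sets (8251 distinct symbols), several to 396 and none to 1193, and genes were named only from probe sets with 1 symbol. Symbols were updated through the gene identifiers of the mouse reference assembly GRCm38.p6, where 10817 of the 10833 were found. The genome build behind the deposited data is not given in the sources used here, so that assembly served only for names and for which genes lie near each other.

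Before the data were examined, 25 gene lists (596 genes, 497 of them measured) were fixed, covering metabolic pathways, fibre types, signalling and markers of other cell types in muscle. The 24 lists with at least 5 measured genes were tested with limma's camera (preset correlation 0.01, 1 probe set per gene, the one with the highest mean), adjusted over the 24 lists. The genes named were also fixed by rule: Crhr2, then 12 genes per direction, and the 2 members of each list with the smallest p, or 4 for a list past its test. As no probe set passed, the 12 per direction were filled by smallest unadjusted p among probe sets with at least a 1.5-fold difference, no overlap between groups and a mean above the median probe set. Other genes named below were chosen after their values were seen. Genes within 20 Mb of Crhr2 were compared with 10000 random stretches of as many neighbouring measured genes by their median absolute moderated t (one-sided). Marker lists of 6 other organs (exocrine pancreas, pancreatic islet, liver, intestine and stomach, kidney, skin and hair) were written after the values had been seen.

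The methods were tested on simulated data built from these arrays. For KO against WT over 12422 probe sets, 200 of them changed, 14.7% of 2-fold, 56.2% of 4-fold, 89.8% of 8-fold and 96.7% of 16-fold changes were recovered over 20 runs, with 6.1 unchanged probe sets called per run. The changes were added on the log2 scale, after the pseudocount. With 200 changed probe sets the adjusted threshold is easier to reach than with few, so these shares do not give the recovery of a lone change. For the oxidative phosphorylation list of 58 genes, camera called 0 of 100 runs with no shift and no correlation between genes. It called 82 of 100 with the observed mean shift and no correlation, and 12 of 100 with no shift and a correlation of 0.108, the value estimated for that list. No run combined the shift with that correlation. The test of genes near Crhr2 passed in 0 of 40 runs with no difference and in 40 of 40 with t values made 1.5 times wider.

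Alternatives were pseudocounts of 3.5 and 56, quantile normalization, median centring, leaving out probe sets under the 40th percentile of mean signal, each array left out in turn, the replicate number as a block, other variance settings, 1 probe set per gene, a 1.5-fold rule, no level filter, camera with an estimated correlation, fry, all probe sets of each gene, and windows of 10 and 40 Mb. Added after seeing the data were the size rule without pancreas and liver genes, lists restricted to members above the median level, a window of 2 Mb, and each array left out with every gene's probe set kept as reported. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.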

Results

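Transcript levels were compared between skeletal muscle of Crhr2 KO and WT littermates without treatment, with 2 arrays per genotype and RNA of 2 mice on each array. Crhr2 encodes the receptor for the urocortin peptides, and the comparison asked which muscle transcripts differ when the receptor is missing. The 4 arrays did not group by genotype as a whole. Across probe sets, which are not independent replicates, the Pearson correlation of log2 signals was 0.964 between the WT arrays, 0.965 between the KO arrays and 0.960 to 0.966 between arrays of different genotype.

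Crhr2 (Entrez gene 12922) was lower in both KO arrays than in both WT arrays. Its brighter probe set read 154 and 192 in WT (mean 173 ± 26.6, SD, n = 2) and 100.4 and 75.1 in KO (mean 87.7 ± 17.9, SD, n = 2), so the KO mean was 50.7% of the WT mean. The log2 fold change was -0.88 ± 0.25 and did not pass adjustment over all probe sets (limma adjusted p = 0.803). An exact two-sided permutation test gave p = 0.333, the smallest value that 2 against 2 arrays allow. The dimmer Crhr2 probe set did not separate the genotypes, at 32.1 ± 18.8 in WT and 29.7 ± 9.90 in KO. The position of either probe set relative to the deleted part of the gene is not given in the sources used here, so these levels are a limited check of the genotype labels. Of the CRF and urocortin genes, 3 were measured and all 3 were lower in KO. Pomc, the precursor of corticotropin, had a log2 fold change of -0.58 ± 0.32. In this list 0 genes passed over all probe sets and 1, Crhr2, passed when adjusted over the list alone.

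**Figure D1:**
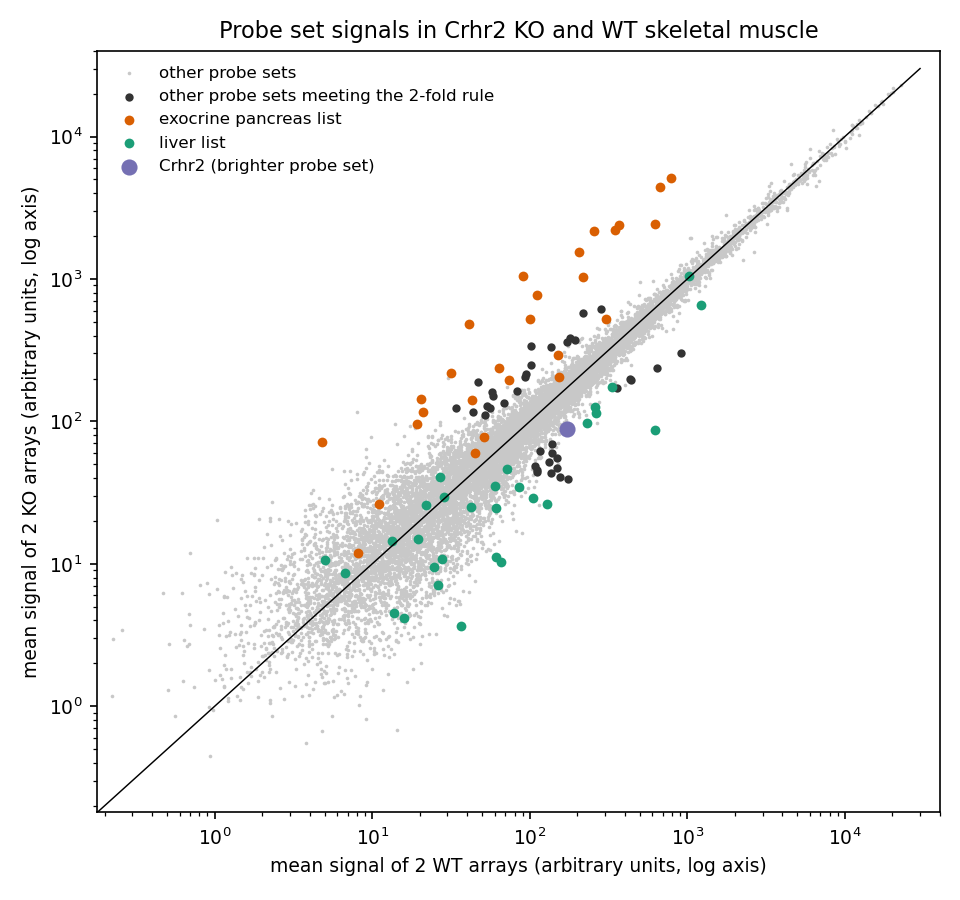
Mean signal of each of the 12422 probe sets in the 2 KO arrays (vertical) against the 2 WT arrays (horizontal), in arbitrary units on log axes, with the line of equality. Colours mark the brighter Crhr2 probe set, probe sets of the exocrine pancreas and liver lists, and the other probe sets that met the 2-fold rule. Pancreatic genes lie above the line and most liver genes below it.

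Of the 12 genes named as higher in KO muscle, Cd59a, Ghitm and Cd59b had the smallest unadjusted p. Cd59a, which blocks the membrane attack complex of complement, read 239 and 194 in WT and 582 and 576 in KO (log2 fold change 1.37 ± 0.15). Its close paralog Cd59b read 101.3 ± 38.3 in WT and 338 ± 34.5 in KO (log2 fold change 1.65 ± 0.26), and probes of such paralogs can share signal. Ghitm, a protein of the inner mitochondrial membrane, differed by 1.09 ± 0.13 on the log2 scale, and by 0.42 ± 0.10 on its other probe set. Rundc3a, Pdlim4, which binds the cytoskeleton, and Sec16a, which organises endoplasmic reticulum exit sites, had log2 fold changes of 1.79 ± 0.38, 1.56 ± 0.36 and 0.59 ± 0.13, with 0.39 ± 0.26 on the other, dim probe set of Pdlim4. The remaining 6 of the 12 were genes of pancreatic acinar cells. They were the lipase Cel (2.93 ± 0.69), the lipase cofactor Clps (2.14 ± 0.36), the zymogen granule protein Zg16 (2.94 ± 0.54), the trypsin-like 2210010C04Rik (2.34 ± 0.54, and 1.24 ± 0.36 on its other probe set) and the chymotrypsins Ctrb1 (1.78 ± 0.39) and Ctrl (0.75 ± 0.14). These signals differed between the KO arrays: Cel read 110.1 and 72.3 in WT, 1741 in KO replicate 1 and 341 in KO replicate 2. In a list of exocrine pancreas genes written after the values were seen, all 22 measured genes were higher in KO on average and 16 separated the genotypes. Their median difference from the WT mean was 2.59 in KO replicate 1 and 0.93 in KO replicate 2 on the log2 scale.

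Of the 12 genes named as lower in KO muscle, Rbp4, Tex261 and Msrb1 had the smallest unadjusted p. Rbp4, the plasma carrier of retinol, read 262 ± 3.89 in WT and 114 ± 7.54 in KO (log2 fold change -1.11 ± 0.18). Serpina1b, an alpha-1-antitrypsin gene with near-identical copies, differed by -0.97 ± 0.21. Pik3cd, the delta catalytic subunit of phosphoinositide 3-kinase, read 176 ± 19.4 in WT and 39.5 ± 15.6 in KO (log2 fold change -1.85 ± 0.32), with -0.60 ± 0.36 on its other, dim probe set. Tmem115, a Golgi protein, differed by -1.66 ± 0.33. The methionine sulfoxide reductase Msrb1, the mitochondrial ribosomal protein Mrps12 and the hydrolase Cmbl differed by -0.80 ± 0.14, -0.79 ± 0.14 and -0.71 ± 0.13. Hypk and the E2F partner Tfdp1 differed by -0.60 ± 0.13 and -0.61 ± 0.14, with -0.35 ± 0.34 and -0.49 ± 0.34 on the other probe sets of Tfdp1. For 3 further genes the probe sets disagreed in sign or size. Junb, a subunit of the AP-1 transcription factor, had a log2 fold change of -1.23 ± 0.27 and of 0.25 ± 0.47 on a dimmer probe set. The protease inhibitor Slpi had -1.41 ± 0.27, with -0.16, -0.09 and 0.36 on its 3 other probe sets. The first of these read 176 ± 72.3 in WT, against 150 ± 23.5 on the named one. Tex261 had -1.06 ± 0.17 (434 ± 84.5 in WT), with -0.07 on its other, brighter probe set (551 ± 49.3 in WT). In a list of liver genes written after the values were seen, 23 of 29 were lower in KO and 15 of these separated the genotypes. The median log2 fold change of that list was -0.64, and its genes were highest in WT replicate 2 in 17 of 29 cases. Albumin (Alb) read 230.0 and 1016 in WT and 78.7 and 95.2 in KO.

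None of these genes passed the test: 0 of 12422 probe sets had an adjusted p under 0.05 (limma, smallest adjusted p = 0.803). At an unadjusted p under 0.05 there were 674 probe sets, 319 higher and 355 lower in KO, where 621 would be expected by chance. The size rule was met by 55 probe sets, 35 higher and 20 lower in KO, against 22 and 44 for the other 2 ways of splitting the 4 arrays into 2 groups of 2. Of the 55, 15 higher probe sets belonged to the pancreas list and 3 lower ones to the liver list. In all, 34.6% of probe sets separated the genotypes, where chance gives 33.3% and the other 2 splits gave 34.9% and 30.5%. The size rule was met by 90 to 114 probe sets when any 1 array was left out: 114 without WT replicate 1, 103 without WT replicate 2, 109 without KO replicate 1 and 90 without KO replicate 2. It was met by 26 with 4 times the pseudocount.

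**Figure D2:**
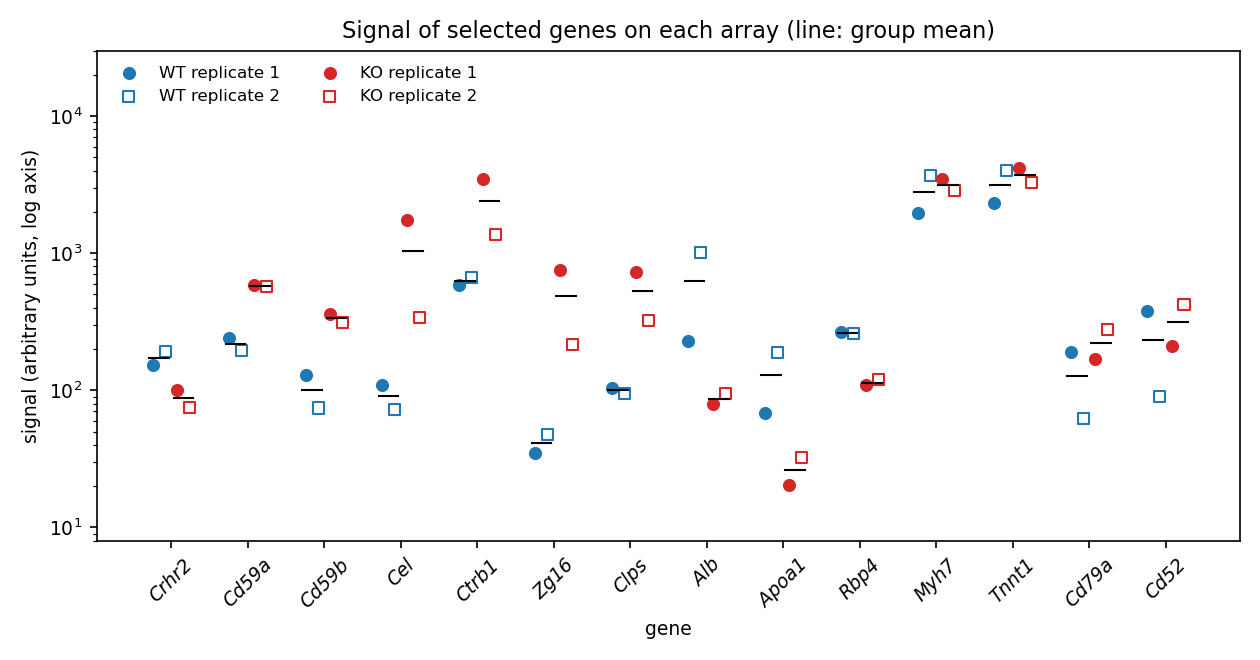
Signal of 14 genes on each of the 4 arrays, in arbitrary units on a log axis; circles are replicate 1 and squares replicate 2 of WT (blue) and KO (red), and lines are group means of 2 arrays. Cd59a and Rbp4 read alike within each genotype, Cel reads 1741 and 341 in the KO arrays, and Alb reads 230.0 and 1016 in the WT arrays.

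Nuclear genes of oxidative phosphorylation stood slightly lower in KO muscle as a group. Of 58 measured genes, 47 were lower and 11 higher, with a median log2 fold change of -0.12 and a mean of -0.10 (camera adjusted p = 0.00315). The adjusted p = 0.876 with an estimated correlation, so the call did not hold there, nor with fry, where the adjusted p was 0.791. The lower genes came from every part of the chain: 15 of 20 genes of complex I, 4 of 4 of complex II, 6 of 7 of complex III, 10 of 13 of complex IV, 10 of 12 of ATP synthase and both cytochromes c and c1. Cox6c, a subunit of cytochrome oxidase, read 6874 ± 121 in WT and 4867 ± 910 in KO (log2 fold change -0.51 ± 0.15). Atp5g2, a subunit of the ATP synthase ring, differed by -0.40 ± 0.12, the dim Cox5a by -0.81 ± 0.31 and Cox6b1 the other way, by 0.68 ± 0.25. Over all probe sets 0 of the 58 genes passed, and 0 passed when adjusted over the list alone. The mean shift of the list on each array was -0.0013 in WT replicate 1, 0.10 in WT replicate 2, -0.10 in KO replicate 1 and 0.0024 in KO replicate 2. The lower level in KO thus rested mainly on WT replicate 2 and KO replicate 1. WT replicate 2 was the highest array for 17 of 29 liver genes, and KO replicate 1 for 21 of 22 exocrine pancreas genes. The mean was -0.15 without WT replicate 1 (adjusted p = 0.00055), -0.08 without WT replicate 2 (adjusted p = 0.149), -0.05 without KO replicate 1 (adjusted p = 0.0494) and -0.15 without KO replicate 2 (adjusted p = 0.00328). Without WT replicate 2 the dim Ndufa1 was read from another probe set, and with the probe sets as reported the mean was -0.05 (adjusted p = 0.229). WT replicate 2 also had the highest mean shift of the slow-fibre genes (0.25, against -0.28 in WT replicate 1) and the lowest of the lymphocyte markers (-0.65). Ratios of 3' to 5' control signals, a measure of RNA integrity and labelling, were higher in both KO arrays than in both WT arrays, at 0.624 and 0.686 in WT and 0.729 and 0.866 in KO for actin, and at 0.889 and 0.914 in WT and 1.04 and 0.988 in KO for Gapdh.

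The other fuel pathways did not pass. Of 26 genes of fatty acid uptake and oxidation, 20 were lower and 6 higher in KO (median log2 fold change -0.09, camera adjusted p = 0.328). Hadh, a dehydrogenase of beta-oxidation, and Fabp3, the muscle fatty acid-binding protein, differed by -0.27 ± 0.11 and -0.38 ± 0.16. Of 24 genes of glycolysis and glycogen, 15 were lower (median -0.04, camera adjusted p = 0.315), among them Ppp1r3c, which targets protein phosphatase to glycogen (-0.45 ± 0.14), and the muscle fructose bisphosphatase Fbp2 (-0.57 ± 0.26). The TCA cycle genes were 12 higher and 10 lower (median 0.03, camera adjusted p = 0.788), with Pdhb at 0.45 ± 0.20 and Dlat at -0.29 ± 0.15, both parts of pyruvate dehydrogenase.

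Contractile genes of slow and fast fibres did not pass the test. Of 13 slow-fibre genes, 7 were higher and 6 lower in KO (camera adjusted p = 0.929), the median of 0.04 and mean of 0.03 being positive where the test's direction was negative. Csrp3 and Ankrd2 differed by -0.30 ± 0.13 and -0.19 ± 0.12. The WT pools differed from each other in these genes: the slow myosin Myh7 read 1968 and 3666 in WT and 3452 and 2872 in KO. The list was lower in KO without WT replicate 1 (adjusted p = 0.00102) and higher without WT replicate 2 (adjusted p = 0.000814), both at the preset correlation of 0.01. The correlation estimated from the 4 arrays was 0.408, and with it the adjusted p of the list over all 4 arrays was 0.972. Of 14 fast-fibre genes, 8 were higher and 6 lower (median 0.02, mean -0.01, camera adjusted p = 0.801), with the fast myosin Myh1 at -0.16 ± 0.12 and Myoz1 at -0.14 ± 0.13. The mean of the fast-fibre list was 0.07 without KO replicate 1 and -0.09 without KO replicate 2. Myogenic, neonatal and denervation genes were lower in 17 of 26 cases (median -0.11, camera adjusted p = 0.725). In that list the cardiac actin Actc1 read 3318 ± 181 in WT and 4494 ± 647 in KO (0.43 ± 0.13), and the stress-responsive Ankrd1 differed by 0.82 ± 0.30.

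**Figure D3:**
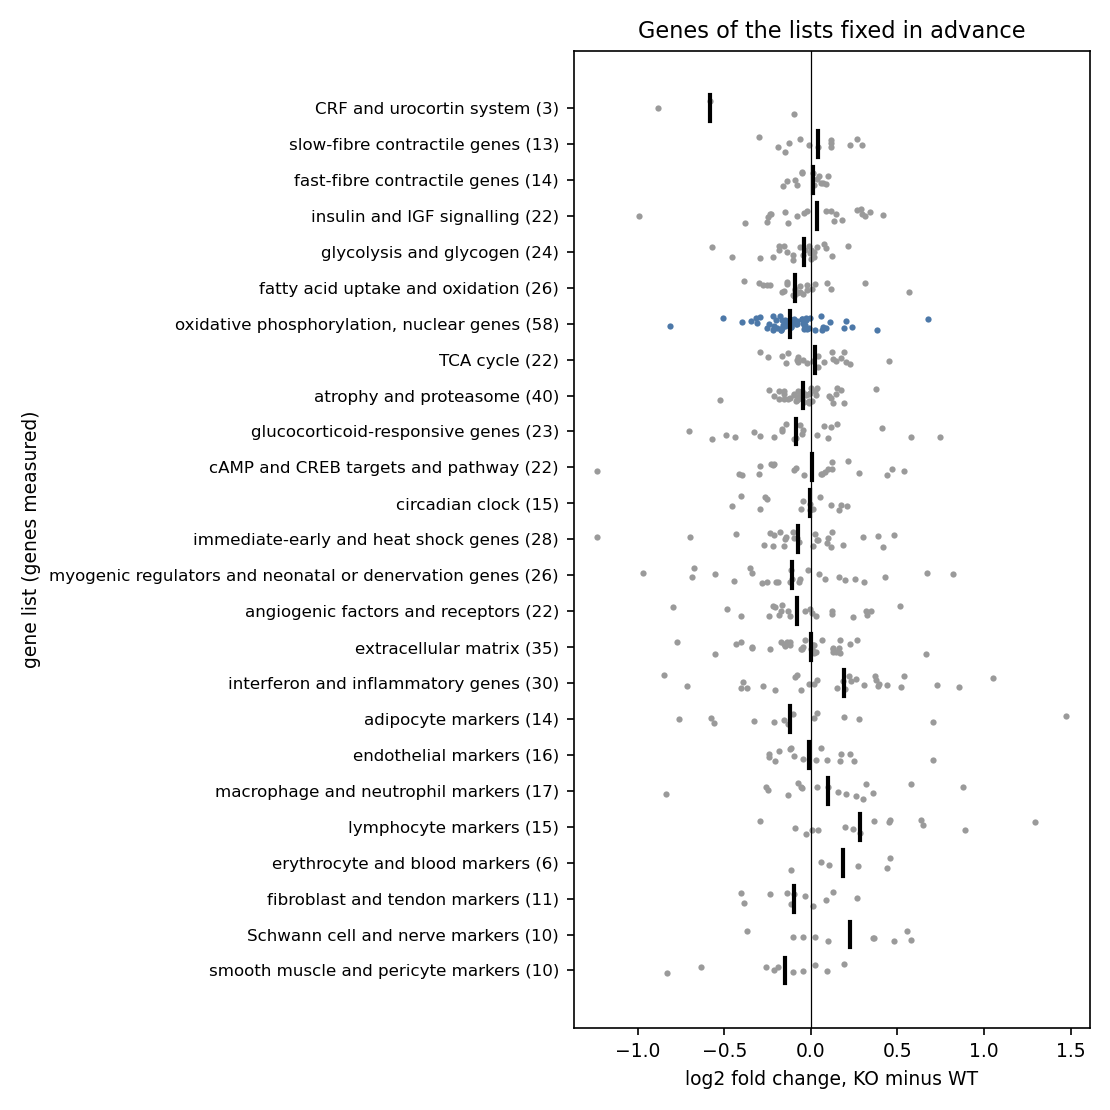
Log2 fold change (KO minus WT) of each measured gene of the 25 lists fixed in advance, with 1 point per gene, vertical bars at list medians and the number of genes in brackets. The 58 oxidative phosphorylation genes (blue) have a median of -0.12. The medians of the other lists lie on both sides of 0, some farther from it and some nearer.

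Lists of hormone signalling and stress did not pass either. Insulin and IGF signalling genes were 11 higher and 11 lower (median 0.03, mean -0.01, camera adjusted p = 0.788). Within it Pik3r1, the regulatory subunit of phosphoinositide 3-kinase, was dim and differed by -0.99 ± 0.32, and the adaptor Grb2 by -0.26 ± 0.12. Glucocorticoid-responsive genes were lower in 15 of 23 cases (median -0.09, camera adjusted p = 0.548), with glutamine synthetase (Glul) at 207 ± 2.29 in WT and 360 ± 78.5 in KO (0.75 ± 0.19) and metallothionein Mt2 at -0.71 ± 0.24. The cAMP and CREB genes were 11 higher and 11 lower (median 0.01, mean -0.05, camera adjusted p = 0.753), with the phosphodiesterase Pde4b at 0.54 ± 0.20 beside Junb. The mean of that list was 0.0009 without KO replicate 1 and -0.11 without KO replicate 2. Immediate-early and heat shock genes were 13 higher and 15 lower (median -0.08, camera adjusted p = 0.725), with Atf3 at -0.70 ± 0.27 beside Junb. Clock genes were lower in 9 of 15 cases (median -0.01, camera adjusted p = 0.725), with Rora at -0.40 ± 0.12 and Cry1 at -0.25 ± 0.17. Atrophy and proteasome genes were lower in 28 of 40 cases (median -0.04, camera adjusted p = 0.615), with the proteasome subunit Psmd8 at 1194 ± 30.6 in WT and 825 ± 29.0 in KO (-0.53 ± 0.10) and Foxo3 at 0.38 ± 0.16. Over all probe sets and adjusted over the list alone, 0 genes of these lists passed.

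Markers of immune cells and adipocytes did not pass the test. Lymphocyte markers were higher in 12 of 15 cases (median 0.28, camera adjusted p = 0.301), with Igha at 1.30 ± 0.64 and the B-cell gene Cd79a at 0.89 ± 0.48. Their mean shift was 0.31 in WT replicate 1, -0.65 in WT replicate 2, -0.01 in KO replicate 1 and 0.35 in KO replicate 2. Interferon and inflammatory genes were higher in 19 of 30 cases (median 0.19, camera adjusted p = 0.473), with Cxcl10 at -0.85 ± 0.37 and Ifit2 at 0.73 ± 0.33, and were also lowest in WT replicate 2. Without WT replicate 1 both lists were higher in KO, with adjusted p = 5.31e-07 for lymphocyte and 0.00055 for interferon genes. Without WT replicate 2 both mean shifts turned negative, at -0.14 for lymphocyte (adjusted p = 0.370) and -0.06 for interferon genes (adjusted p = 0.413), and the interferon mean was -0.03 without KO replicate 2 (adjusted p = 0.908). These p use the preset correlation of 0.01; the correlation estimated from the 4 arrays was 0.653 for lymphocyte and 0.210 for interferon genes, and with it the adjusted p over all 4 arrays was 0.876 for both. Macrophage and neutrophil markers were 10 higher and 7 lower (median 0.10, camera adjusted p = 0.725), with Fcgr3 at 0.88 ± 0.34 and Adgre1 at -0.84 ± 0.36. Their mean of 0.09 was 0.25 without WT replicate 1 (adjusted p = 0.109) and -0.07 without WT replicate 2 (adjusted p = 0.472). Adipocyte markers were 6 higher and 8 lower (median -0.12, camera adjusted p = 0.725), and their mean of -0.01 was 0.20 without WT replicate 1 (adjusted p = 0.407) and -0.22 without WT replicate 2 (adjusted p = 0.0867). Within them Cidea, a lipid droplet protein of brown fat, read 26.9 ± 16.6 in WT and 94.9 ± 2.49 in KO (1.48 ± 0.40), and Pck1, which makes glycerol precursors in fat, differed by 0.71 ± 0.20.

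Vascular, matrix and nerve genes showed no shift past the threshold. Endothelial markers were 8 higher and 8 lower (median -0.01, mean 0.03, camera adjusted p = 0.753), with endomucin (Emcn) at 113 ± 14.4 in WT and 193 ± 16.8 in KO (0.70 ± 0.21) and Sox18 at 0.25 ± 0.18. Angiogenic factors and receptors were lower in 13 of 22 cases (median -0.08, camera adjusted p = 0.753), with the dim Fgf2 at -0.79 ± 0.37 and Pdgfa at 0.24 ± 0.13. Smooth muscle and pericyte markers were lower in 7 of 10 cases (median -0.15, camera adjusted p = 0.328), with Pdgfrb at -0.63 ± 0.22 and Cnn1 at -0.83 ± 0.49. Extracellular matrix genes were 18 higher and 17 lower (median 0.00, mean -0.05, camera adjusted p = 0.753), with fibronectin (Fn1) at -0.34 ± 0.13 and Lama2 at -0.55 ± 0.27. Fibroblast and tendon markers were lower in 7 of 11 cases (median -0.10, camera adjusted p = 0.725), with Mfap5 at -0.40 ± 0.23 and Pdgfra at -0.39 ± 0.24. Schwann cell and nerve markers were higher in 7 of 10 cases (median 0.23, camera adjusted p = 0.473), with Mag at 0.58 ± 0.32 and Nefm at -0.37 ± 0.22. Blood markers were higher in 5 of 6 cases (median 0.19, camera adjusted p = 0.473), with Hba-a1 at 0.46 ± 0.14 and Bpgm at -0.11 ± 0.12. Several of these means turned with the WT array left out. Without WT replicate 1 and without WT replicate 2 the mean was 0.04 and -0.14 for matrix genes, 0.05 and -0.22 for fibroblast and tendon markers (-0.08 over all arrays) and 0.07 and -0.02 for endothelial markers. The Schwann cell and nerve mean of 0.19 was 0.05 without WT replicate 1, 0.34 without WT replicate 2, 0.30 without KO replicate 1 and 0.09 without KO replicate 2. In none of the 24 tested lists did a gene pass over all probe sets or adjusted over the list alone.

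Genes near Crhr2 on chromosome 6 were examined because a targeted allele carries linked DNA of the strain in which it was made. Inmt, the nearest measured gene with an unadjusted p under 0.05 in assembly GRCm38.p6, read 646 and 648 in WT and 509 and 407 in KO (log2 fold change -0.49 ± 0.14). The nearby Adcyap1r1, the PACAP receptor gene, was dim and differed by -1.33 ± 0.28, and Fkbp9 differed by -0.61 ± 0.16. Within 20 Mb, 8 of 138 measured genes, each read from 1 probe set, had an unadjusted p under 0.05 (limma). In a fit of 1 probe set per gene, 480 of 8251 genes did, and 5.4% of all probe sets did. Of the 8, 2 met the size rule, the pancreatic genes Prss2 and 2210010C04Rik. Inmt, Adcyap1r1 and Fkbp9, also among the 8, lay within 2 Mb of Crhr2. The median absolute moderated t of the 138 genes was 0.715, against a median of 0.756 for random stretches (one-sided permutation p = 0.749).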

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

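The window of 2 Mb, the restriction of lists to brighter members, the removal of pancreas and liver genes and the repeat of each left-out array with the probe sets as reported were chosen after seeing the data. In every setting run, 0 probe sets passed the adjusted threshold, with smallest adjusted p from 0.0633 without KO replicate 2 to 0.924 without WT replicate 2. Leaving out an array leaves 1 array in a group, which is then assumed to vary like the other group. At an unadjusted p under 0.05 there were 664 to 831 probe sets with 1 array left out and 410 with dim probe sets left out, where fewer were tested. The 2-fold rule gave 55 probe sets as reported, 90 to 114 with 1 array left out, where fewer arrays have to separate, 26 with 4 times the pseudocount and 25 with dim probe sets left out, which raises the median level required. It gave 221 at 1.5-fold and 247 with no level filter, both looser rules, and 37 without pancreas and liver genes (20 higher, 17 lower). Of the 55, 24 were shared with the larger pseudocount, 25 with the dim probe sets left out and 39 to 41 with each array left out. The log2 fold change of the brighter Crhr2 probe set stayed negative in every setting run, at -0.70 to -1.06 with 1 array left out. Its signals did not overlap between the genotypes, so leaving out 1 array could not turn the sign. The dimmer probe set was not followed.

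The number of lists past the threshold was 1 as reported, 1 to 4 with 1 array left out, 0 with an estimated correlation and 0 with fry. For oxidative phosphorylation the adjusted p was 0.00055 to 0.149 with 1 array left out (0.000532 to 0.229 with the probe sets as reported; mean log2 fold change -0.10 over all arrays, -0.05 to -0.15 with 1 left out), 0.876 with an estimated correlation and 0.791 with fry, and 0.00222 to 0.0151 in the other settings. Without WT replicate 2 the 1 list past was slow-fibre genes (adjusted p = 0.000814, and 0.000814 to 0.962 with each array left out; 0.00067 to 0.974 with the probe sets as reported). Their mean was 0.30 there and 0.03 as reported, both higher in KO, while camera's direction as reported, with no call, was lower. The cause was not tested. For the 73 named genes, 0 of 868 recomputed values changed sign. The 24 ranked genes were picked for no overlap between the genotypes, so leaving out an array could not turn their sign. List members were picked for small p, so the count says little on stability. Of 430 list values, 46 had another camera direction than reported, in lists with no call as reported. The labels link same-numbered replicates by a number alone, and how they were handled is not given. The correlation of their deviations across probe sets was 0.00345, which does not settle whether they were handled together. The replicate block gave 0 probe sets past the threshold, 740 at an unadjusted p under 0.05 and an adjusted p of 0.00258 for oxidative phosphorylation, and changed no call. Probe sets below the median level varied most: the SD of log2 differences between the WT arrays was 0.617 there and 0.392 above it.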

Other observations

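The tests of equal effect in both KO pools and of cross-hybridisation, the organ lists and the window of 2 Mb were chosen only after the result was seen. Of 10 skin and hair genes, 7 had their lowest signal in WT replicate 2, and Krt15 had its highest there. Keratin 10 (Krt10) read 389 and 36.8 in WT and 351 and 425 in KO, and Krtdap read 175 and 20.9 in WT and 119 and 221 in KO. Of the 10 genes, 8 were higher in KO, with a median log2 fold change of 0.33. Sprr1b, a protein of the cornified envelope, read 1429 ± 38.6 in WT and 1989 ± 71.6 in KO (log2 fold change 0.47 ± 0.10). WT replicate 2 was also lowest for Cd52, a lymphocyte surface gene (376 and 90.2 in WT, 211 and 421 in KO), and highest for Alb.

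The medians of the other organ lists lay near 0. The 9 pancreatic islet genes had a median log2 fold change of -0.03, the 13 genes of intestine and stomach 0.07 and the 6 kidney genes 0.00. Within the islet list the insulin gene Ins2 read 30.8 and 31.0 in WT, 113 in KO replicate 1 and 5.46 in KO replicate 2. KO replicate 1, the array with the highest exocrine signals, was the highest for 3 of the 9 islet genes, and 0 of the 9 separated the genotypes. Among further genes that met the 2-fold rule, the securin gene Pttg1 read 559 and 1267 in WT and 143 and 462 in KO, and the opioid precursor gene Penk read 88.3 and 27.5 in WT and 159.5 and 160.6 in KO.

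Exocrine pancreas genes were higher in KO on average. Cross-hybridisation within the serine protease family alone is argued against by 15 pancreatic genes outside that family. Their median log2 difference from the WT mean was 2.47 in KO replicate 1 and 0.43 in KO replicate 2. RNA from exocrine pancreas in the KO pools remains a candidate explanation. Of the 12 list genes that had not met the rule, 11 were also higher in KO replicate 1 (median 1.27, and 0.33 in KO replicate 2). These genes were not a separate test, because the list was written after the values were seen. Among them, Klk1 (log2 fold change 1.92) and Rnase1 (2.02) missed the 2-fold rule only through their low level. Pancreatic genes that vary together could also be high there under an effect of genotype. The excess over the WT mean was a median of 5.22 times larger in KO replicate 1 than in KO replicate 2 over 13 of 14 bright genes, Reg1 having none in KO replicate 2, and ranged from 1.61 for Ctrl to 13.1 for Pla2g1b, whose excess in KO replicate 2 of 7.56 was under its WT SD of 9.74; the range that 1 source of RNA would give was not tested. An effect of genotype of 1 size in both pools cannot be told apart from these: the KO replicates differed by a median of 1.80 on the log2 scale over the 10 genes that met the 2-fold rule, outside the central 99% of -1.28 to 1.18 for single probe sets above the median level, but those genes were picked for the pattern and 2 pools per genotype do not show how far genes that vary together differ between pools.

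Liver genes were lower in the KO pools. RNA from liver in WT replicate 2 is a candidate explanation for the high values of that array. Of the 26 list genes outside the 2-fold rule, 21 were higher in that array than the KO mean. Their median log2 difference was 1.06, against 0.28 in WT replicate 1. These genes were not a separate test, because the list was written after the values were seen. Among them, Apoa1 (log2 fold change -1.69) and Kng1 (-1.48) missed the 2-fold rule only through their low level. The brightest list genes had another order: Cyp2e1 was lowest in WT replicate 2 (1484 and 563 in WT, 1008 and 1095 in KO), and Hp was higher in WT replicate 1 than there (1505 and 934 in WT, 758 and 547 in KO). Liver RNA in WT replicate 2 also leaves open WT replicate 1. That array lay above both KO arrays for 17 of 29 liver genes, as for Alb, Rbp4 (264 and 259 in WT) and Mup3 (76.2 and 45.1 in WT, 8.02 and 14.3 in KO). An effect of genotype on these genes was not tested apart from this and stays open.

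Strain DNA linked to the targeted allele was weighed for the genes near Crhr2. The one-sided permutation test over the window gave p = 0.749, and its observed median lay below that of random stretches by less than their spread (95th percentile 0.905), so an effect on few genes cannot be told apart from none in these 4 arrays. The p was 0.808 at 10 Mb, 0.262 at 40 Mb and 0.227 over 12 genes at 2 Mb. Inmt, Adcyap1r1 and Fkbp9 were all lower in KO, and an effect of genotype on them stays open as well.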
